A study of Mus musculus with 10 samples.

How the data were processed

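The series holds 10 samples of mouse naive B cells and plasma cells, of which 6 had files used here: 1 library per cell type for RNA-seq, ATAC-seq and TCC. The ChIP-seq samples for H3K36me3 and H3K4me2 were not analysed here. Samples were grouped by their titles. Per the labels' protocols, naive B cells for RNA-seq and ATAC-seq were CD23+ IgD+ cells sorted from spleen, and ATAC-seq used 50000 cells per library. Those for TCC were purified with beads against CD23. The labels of the plasma cells conflict. For RNA the source field names activation in culture and the extraction protocol a bone marrow sort. For TCC the source field names ex vivo cells and the protocol a culture of 3 days with 10 µg/ml LPS. No reading of either was assumed.

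Per the submitters' processing notes, the tools were Bowtie, HOMER, TopHat, Picard, MACS 1.4 and kallisto and the genome build was mm9. Other versions, filters and any pooling are not given in the sources used here. The deposited RNA files hold the authors' kallisto estimated counts and TPM per transcript, per the file headers. Each deposited ATAC peak has 1 score by the authors' peak caller, used only to rank and describe peaks within a list, and the values fit -10 times the log10 of a p-value with a lowest value of 50.01. The deposited contact maps hold a signal balanced by the authors to equal row sums, in bins of 2 Mb and 500 kb. The deposited interaction lists of 1 Mb bins give read pair counts, the expected reads and other values of the background model, a Z-score and a p-value corrected by the false discovery rate, per the file headers. Pairs of bins on different chromosomes were listed in both orders there, and each was counted once. The bin order of the maps was read from the empty bins that open each chromosome. It gave chromosomes 1 to 19 and X as the first 1328 of 1331 bins, and the last 3 were left out of the comparisons.

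For RNA, transcript values were summed to 26599 genes. The ratio was log2 of plasma over naive TPM with a pseudocount of 1, which understates the change of low genes, centred on the median of genes with at least 5 TPM in both libraries. A gene was called at a centred ratio of at least 1 or at most -1 with at least 5 TPM in 1 library. With 1 library per group there was no test, and exact Clopper-Pearson intervals on the rounded estimated counts cover counting error only, since reads without molecular identifiers are not independent molecules. Of 565 entries in 27 gene lists, 558 were matched. List medians used members with at least 1 TPM in 1 library and were ranked among 10000 random lists matched in 20 bins of mean expression. TMM factors from edgeR 4.0.16 on the rounded estimated counts were 1.28 and 0.783.

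ATAC peaks were shared where they overlapped by at least 1 base, and peaks at loci were counted with 20 kb on each side. Both maps were scaled to the same mean row sum. Whole read pairs behind the 500 kb maps were recovered from the steps of the low values: 99.9% of nonzero entries between chromosomes lay within 0.05 of a whole number in both maps. Of 59953 naive and 59041 plasma listed interactions compared, 99.99% and 100.0% had the same read pairs in the deposited lists. A bin was used for components and loci where its share of nonzero entries with other chromosomes was at least 0.5 of the median in both maps, which left 1286 bins of 2 Mb and 4662 of 500 kb, and few bins of chromosome X. Ratios of single bin pairs used a pseudocount of 0.1 of the mean contact between chromosomes. The compartment component was the first principal component of the correlation of observed over expected contacts per chromosome, with its sign set by the number of ATAC peaks. A bin switched where the sign differed and both values exceeded 0.25 SD. The 16 loci were placed at approximate mm9 positions known beforehand, because the annotation used here is of another build and no coordinates were converted. The relation of the component with RNA needs an mm9 annotation and was not run.

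The named genes were a fixed panel of 16, the 3 members with the largest change in each list outside the 2.5 to 97.5 percentiles, and the 5 largest gains and losses among genes with at least 50 TPM, without immunoglobulin genes. The named regions were the 16 loci, the 5 highest-scoring peaks of each cell type alone, and the 10 pairs of bins with the largest gain and loss. Other genes, the contact classes, the pairs with at least 50 read pairs, the bin filter, the pseudocount of contacts and the flank of loci were chosen after values were seen. Single values of some genes and of 1 locus are not reported here. The lists, loci, comparisons and 43 alternatives were fixed before the data were examined, and 5 more were added.

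Gene calls, list medians, compartment switches, the rotation test, locus contacts and peak overlap were tested on simulated data. The share of contacts between chromosomes, the slopes, the contact classes and the comparison of interaction lists were not. Among 9946 genes, 50 of 50 simulated changes of each fold (2.5, 4, 0.4 and 0.25) were called and 5 of 9746 unchanged genes. Both simulated libraries were drawn from the naive counts with counting error alone, without differences between preparations or the shift in composition between the real libraries. The rates of these gene calls therefore do not carry over to the real libraries. Random lists lay outside the 2.5 to 97.5 percentiles in 6.50% of 200 cases. The simulated switches were found in 6 of 6 bins with 0 of 294 others. These rates for switches do not carry over to the real maps, where the number of switches depended on the minimum size of the component. For locus pairs, a simulated 2-fold loss had an interval below 0 in 52.8% of 5700 cases, and 3.44% of unchanged pairs had an interval without 0. Rotations gave a p under 0.05 in 3 of 60 unrelated tracks. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.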

Results

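Gene expression, chromatin accessibility and chromosome contacts were measured in mouse naive B cells and in plasma cells, the antibody-secreting cells that B cells become. The strain was C57BL/6. Each of 3 assays (RNA-seq, ATAC-seq of accessible chromatin, and TCC, a tethered form of the Hi-C contact assay) had 1 library per cell type, so no difference given here has a replicate check. The RNA libraries held 37.0 M estimated counts in naive B cells and 43.5 M in plasma cells. The contact maps held 36.5 M and 38.1 M read pairs, recovered from the balanced values. The depth of the ATAC libraries is not known from the peak lists. Intervals are 95% intervals and cover counting error only. The cell sources differed between assays. Per the labels, the plasma cells for ATAC-seq were sorted from bone marrow. The labels of the other plasma libraries conflict: for RNA they name both an in vitro activated source and a bone marrow sort, and for TCC both ex vivo cells and a culture of 3 days with 10 µg/ml lipopolysaccharide (LPS) sorted by a Blimp reporter. The series title names an inter-chromosomal hub and the unfolded protein response, and the comparisons below address how expression, accessibility and contacts differed between the cell types.

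Plasma cells had far more transcripts of the plasma cell regulators and of the secretory pathway, and far fewer of the naive B cell program. Prdm1, which encodes the repressor Blimp-1, was listed at 2.29 TPM in naive B cells and 249 TPM in plasma cells, a centred log2 ratio of 7.23. Xbp1, the transcription factor activated by IRE1, was higher by 4.08 (109 to 939 TPM), the elongation factor Ell2 by 3.63 and Irf4 by 2.17. Pax5, the B lineage commitment factor, was lower, with a log2 ratio of -3.39 (346 to 15.7 TPM), as were Bach2 at -3.01 and Bcl6 at -2.66. The ratio of estimated counts, centred and without a pseudocount, had intervals of 7.38 to 7.75 for Prdm1, 4.20 to 4.30 for Xbp1 and -3.43 to -3.23 for Pax5. Immunoglobulin genes took 5.08% of TPM in naive B cells and 35.1% in plasma cells.

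Of 10219 genes with at least 5 TPM in 1 library, 1634 were at least 2-fold higher in plasma cells, 2257 were at least 2-fold lower and 6328 lay between, after centring on the median of the 7495 genes with at least 5 TPM in both libraries. The higher genes were 42.0% of those called. That centring removed a shift of -0.99, and all directions are relative to it. Without centring the higher share was 11.9% (792 higher, 5890 lower). With TMM factors of the counts applied to TPM it was 26.3% (1235 higher, 3454 lower). That setting mixes 2 scales, so its excess of lower genes is not the result of a TMM normalisation of the counts. The majority turned to higher genes with a pseudocount of 5 TPM (52.8%, 1387 higher and 1239 lower) and with no TPM filter (60.7%, 3680 higher and 2385 lower).

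The genes of the unfolded protein response stood high as a group. All 22 measured members of the IRE1 and XBP1 list were at least 2-fold higher, with a median log2 ratio of 3.01, above 99.99% of 10000 random lists of the same size and expression. Sdf2l1 was higher (16.6 to 215 TPM), as were Sec24d by 4.52 and Creld2 by 4.23. In the list of the PERK and ATF4 arm 22 of 23 members were at least 2-fold higher (median 2.93, percentile 100). Asparagine synthetase, Asns, was higher by 7.10 (1.12 to 146 TPM), the glutathione-degrading Chac1 by 5.69 and Atf3 by 5.22, while Atf4 itself was higher by 1.43 and Ddit3, which encodes CHOP, by 1.48. In the ATF6 and chaperone list 15 of 17 members were at least 2-fold higher (median 2.70), among them Manf at 4.16 and the chaperone Hspa5 at 3.22, which went from 314 to 1483 TPM. The median was 1.91 for endoplasmic-reticulum-associated degradation (13 of 18 members, Derl3 at 5.31, Edem2 at 3.15, Sel1l at 3.01). It was 2.54 for translocation and glycosylation (24 of 31, Ssr2 at 3.59, Sec61g at 3.45, Ddost at 3.36) and 1.47 for traffic to the Golgi (21 of 30, Lman1 at 3.58, Kdelr3 at 3.56). The lists share members and are not independent: Manf, Creld2, Sdf2l1, Herpud1, Hyou1, Pdia4, Pdia6 and Dnajc3 are in both the IRE1 and XBP1 and the ATF6 lists, and Sec24d, Sec61g, Edem2 and Sel1l are each in 2 of the lists. The ATF6, degradation, translocation and traffic lists each stood above all of their random lists.

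Among 10 measured plasma cell regulators 7 were at least 2-fold higher and 1, Myb at -1.19, was lower (median 2.22, percentile 99.97). In the list of plasma cell surface and secretion genes 10 of 18 were higher and 3 lower, Cd38 at -1.85, Cxcr4 at -1.14 and Itga4 at -1.07 (median 1.20, percentile 99.89). The higher members included Derl3, Fkbp11 at 4.94, the chaperone-like Mzb1, which went from 290 to 3554 TPM, and the immunoglobulin joining chain Jchain at 3.55. Sdc1, which encodes the sort marker CD138, was at 11.1 TPM in naive B cells and 5.38 TPM in plasma cells. Its centred ratio of 0.06 had a count interval of -0.16 to 0.18, and is below 0 without centring and with TMM factors applied to TPM. The naive B regulators had a median of -1.94, below all random lists, with 13 of 17 members at least 2-fold lower, led by Spib at -5.17, Pax5 and Ciita at -3.14. In the list of naive surface and signalling genes 19 of 23 were lower (median -2.37, percentile 0), including the IgE receptor Fcer2a at -6.11, the IgM receptor Fcmr at -4.54 and the exit receptor S1pr1 at -4.17. Fcer2a encodes CD23, by which the naive B cells were sorted, so its ratio was in part set by the sort. MHC class II genes were lower in 9 of 11 cases (percentile 0), with H2-Oa at -4.03 and H2-DMb2 at -2.74.

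Genes of the cell cycle, glycolysis and lipid synthesis were also higher in the plasma RNA library, in which mitochondrial genes took 1.66% of TPM against 6.52% in naive B cells. Of 30 cell cycle genes 25 were at least 2-fold higher (median 2.91, percentile 100), with Ube2c at 4.22, Ccnb1 at 3.84, Cdc20 at 3.69 and Mki67 at 3.37. Glycolytic enzymes had a median of 2.37 (12 of 15 higher, percentile 99.94), with Pgk1 at 3.76, Tpi1 at 3.31 and Pkm at 3.16. Genes of cholesterol and lipid synthesis had a median of 2.28 (17 of 25, percentile 100), with Fdps at 4.32, Scd2 at 3.45 and Insig1 at 3.43. The list of B cell activation by LPS had a median of 1.09 (11 of 21 higher, 3 lower, percentile 99.99), with Bcl2l1 at 5.02, Il2ra at 3.74 and Cd69 at 2.47. Histone genes had a median of 1.26 (6 of 9, percentile 98.73), with Hist1h1c at 2.55, H2afz at 1.75 and Hist1h4i at 1.70. Interferon response genes had a median of 0.57 at the percentile 99.20, which became -0.41 without centring and 0.035 at the percentile 63.3 with members of at least 5 TPM, and their members went both ways: Isg20 at 4.35, Isg15 at 4.27 and Ifi27l2a at 3.05 were higher, while Ifit3 was at -3.21. The medians of ribosomal proteins (0.80, percentile 41.5) and oxidative phosphorylation (0.98, percentile 94.9) lay within their random lists, and both were below 0 without centring. Against random lists matched on naive expression alone they lay at the percentiles 99.62 and 100.

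Markers of T and NK cells, of neutrophils and monocytes, and of erythroid and stromal cells were lower in the plasma library. The naive library held such transcripts itself, so these ratios also depend on other cells in the naive sample and are not shown to be a property of plasma cells. T and NK cell markers had a median of -1.22 with Lck at -2.76, and Trbc2 and Trbc1 were listed at 0 in plasma cells. Neutrophil and monocyte markers had a median of -1.14, with Lyz2 at 55.2 TPM in naive B cells and 0.24 TPM in plasma cells, Csf1r at 42.5 and 0.014 TPM, and Adgre1 at 19.2 and 0.17 TPM. Erythroid and platelet markers had a median of -2.01, and Hba-a2, Hbb-bs and Hba-a1 were listed at 0 in plasma cells. With a pseudocount of 5 TPM the neutrophil and monocyte median was 0.067, the T and NK median -0.017 and the erythroid median -0.77, each still below the central 95% of random lists. Of 3 measured stromal and endothelial genes Pecam1 was at -2.74 and Vcam1 was listed at 0 in plasma cells. Dendritic and basophil markers lay within their random lists (median -0.18, percentile 15.8), but their direction depended on the setting: the median was 2.70 (percentile 99.1) with members of at least 5 TPM and -2.33 (percentile 0.545) with a pseudocount of 0.1 TPM. Beyond the immunoglobulin genes, the largest gains among genes with at least 50 TPM in 1 library were Xist at 7.53, the cytokine gene Il10 at 7.48, Tmed6 at 7.37, Prdm1 and Asns. The largest losses were Gm17241 at -7.00, the ligand gene Icosl at -6.68, Gm11029, the gene of the naive sort marker, Fcer2a, and the Y-linked Eif2s3y. Gm11029 and Eif2s3y were listed at 0 in plasma cells, and Eif2s3y was at 104 TPM in naive B cells. Xist is made from the inactive X chromosome of females, so sex-linked transcripts moved with the comparison between these libraries.

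**Figure D1:**
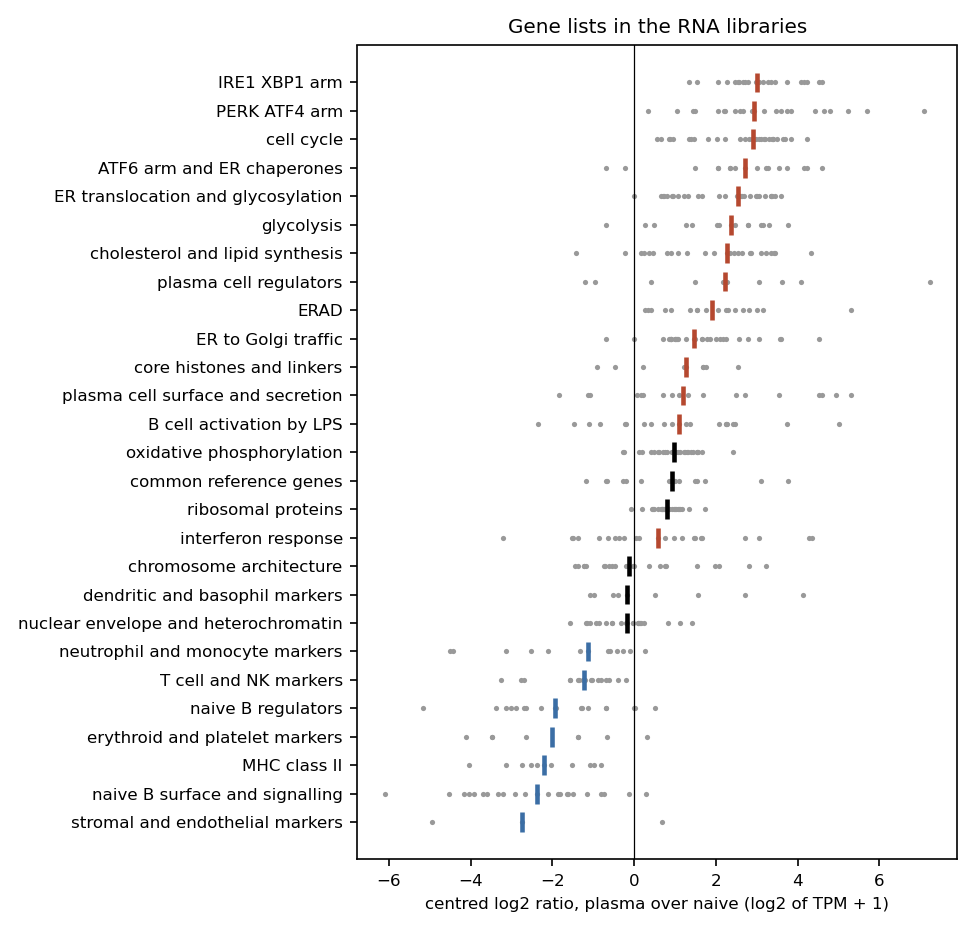
Centred log2 ratio of plasma over naive TPM for the members of each gene list (grey points, 1 library per cell type) and the list median (bar). Red and blue bars mark medians above or below the central 95% of random lists, and black bars lie between. The IRE1 and XBP1 list has the highest median, 3.01, and the stromal list, with 3 measured genes, the lowest, -2.74.

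Most accessible sites were found in both cell types, while the immunoglobulin light chain locus Igk had fewer peaks in plasma cells and Xbp1 had more. Igk (chromosome 6, 67490001 to 70710000, mm9) held 75 naive and 30 plasma peaks, and Igh (chromosome 12, 114320001 to 117260000) held 24 and 14, although the length covered at Igh was 34.9 kb in naive B cells and 38.8 kb in plasma cells. Xbp1 held 3 naive and 6 plasma peaks and Ern1, which encodes IRE1, held 3 and 7. Of the plasma peaks at these loci, 3 at Xbp1 and 4 at Ern1 overlapped no naive peak. Irf4 held 6 naive peaks and 1 plasma peak, with no overlap, and Prdm1 3 and 1, although the RNA of both genes was higher in plasma cells. The highest-scoring naive peak overlapped no plasma peak at Prdm1 (480), Irf4 (663), Ell2 (797) and Hspa5 (953), while at Xbp1, Ern1 and Atf4 it did. Whether such sites were closed in plasma cells or only missing from the plasma list was not tested. These windows rest on approximate positions, and the 500 kb bins of the same loci did not always follow them: they held 14 naive and 19 plasma peaks at Prdm1, 13 and 16 at Irf4 and 17 and 17 at Ern1. Pax5 held 7 and 4 peaks, Bach2 19 and 20, and Ebf1 16 and 20, against 36 and 32 in the 500 kb bins of Ebf1.

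The naive list had 29868 peaks, of which 20533 (68.7%, exact binomial interval 68.2 to 69.3%) overlapped a plasma peak by at least 1 base. The plasma list had 30475 peaks, of which 20364 (66.8%, 66.3 to 67.4%) overlapped a naive peak. Peaks found in 1 list alone had lower scores, with a median of 95.8 in naive B cells against 327 for shared peaks, and 114 against 385 in plasma cells. The plasma list covered 64.4 Mb and the naive list 56.3 Mb. The highest-scoring naive peak without a plasma peak lay on chromosome 15 at 57722874 to 57725162 (score 1324), followed by peaks on chromosome 12 at 77652597, chromosome 13 at 33025778, chromosome 5 at 150437644 and chromosome 10 at 86166687. The highest-scoring plasma peak without a naive peak lay on chromosome 13 at 114939749 to 114943047 (score 1236), followed by chromosome 6 at 51236470 and chromosome 1 at 62246144, 153646656 and 153490080. A library of each cell type with an unknown depth leaves open how many peaks stayed below the calling threshold.

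In the plasma map chromosomes made fewer contacts with each other and fewer at long range within themselves. Contacts between chromosomes made up 24.3% of the balanced naive map and 20.1% of the plasma map, a difference of -4.21 percentage points. The share was lower in plasma cells on 20 of 20 chromosomes, by -7.51 to -1.20 points (mean difference -4.60, SD 1.88 over chromosomes). All chromosomes of a cell type come from 1 library, and each such contact counts for both chromosomes. Neither the count nor the SD therefore measures a spread between replicates. Contact within chromosomes fell with distance with a slope of -0.52 in naive B cells and -0.69 in plasma cells. The slopes were fitted on a log-log scale from 2 Mb to 50 Mb in 2 Mb bins. The slope was steeper in plasma cells on 20 of 20 chromosomes (SD of the difference 0.064), again from 1 library per cell type. The slopes between 2 Mb and 20 Mb differed by -0.00051, but the curves did not run parallel there: the log2 ratio of plasma over naive contact was 0.28 at 2 Mb, 0.18 at 5 Mb and 0.35 at 17.5 Mb. Plasma contact was higher at 1 Mb (19.5 against 14.4) and at 18 Mb (2.19 against 1.75), and lower from 33.5 Mb on. At 60 Mb it was 0.559 against 1.09, a log2 ratio of -0.96.

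**Figure D2:**
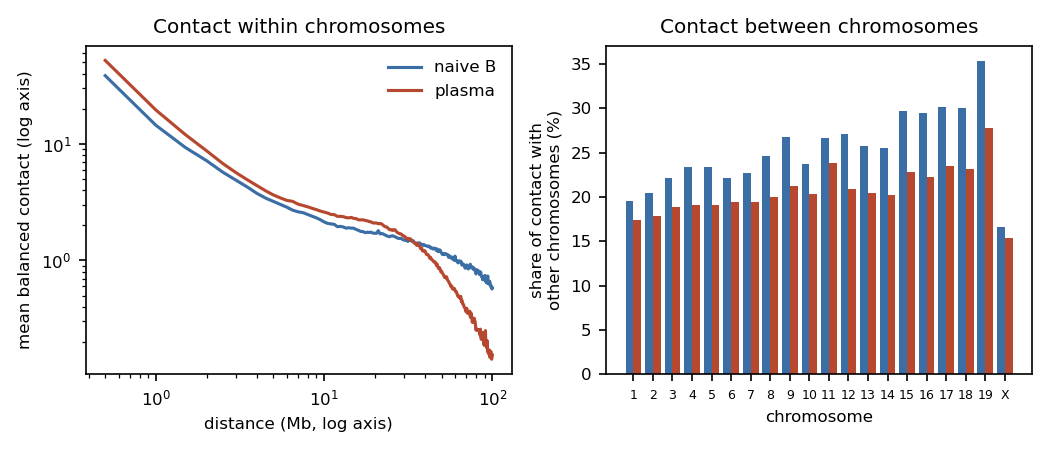
Left, mean balanced contact against distance within chromosomes in Mb, both axes logarithmic, for the naive (blue) and plasma (red) maps. Right, the percentage of each chromosome's contact made with other chromosomes. The curves cross near 33.5 Mb, and the plasma bar is lower on 20 of 20 chromosomes.

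The contacts that remained between chromosomes were arranged differently, in classes of 2 Mb bins chosen after the maps were seen. Contacts between the centromere ends of different chromosomes, the bins from 2 to 12 Mb, were 1.99 times the mean contact between chromosomes in naive B cells and 2.98 times in plasma cells, and they were higher in plasma cells in 166 of 171 pairs of autosomes. Contacts between the telomere ends went from 1.47 to 2.47 times the mean (170 of 171 pairs). Contacts of a centromere end with a telomere end went from 1.09 to 0.579 times the mean, lower in 171 of 171 pairs. The pairs share chromosomes and libraries, so these counts measure no spread between replicates. Contacts between bins of strong A compartment, the active part of the genome, went from 2.61 to 2.24 times the mean, and contacts of strong A with strong B bins from 0.333 to 0.481.

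**Figure D3:**
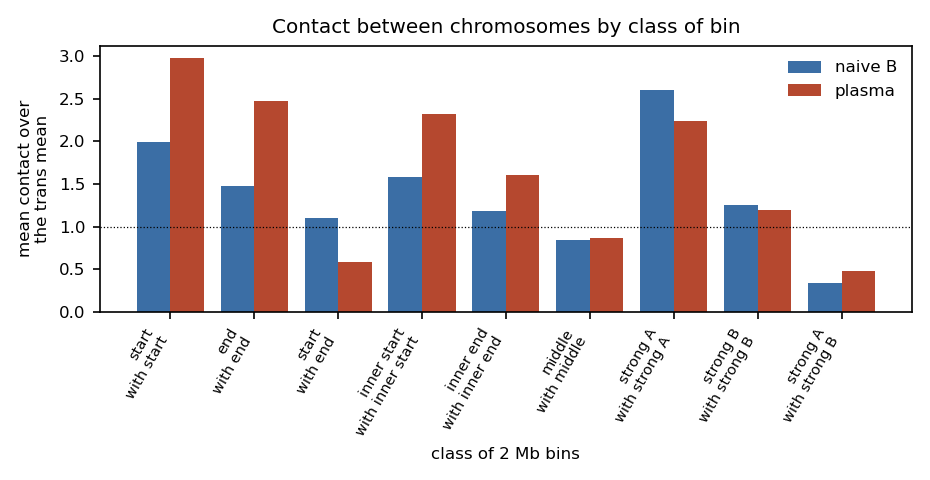
Mean contact between chromosomes, divided by the mean of all contacts between chromosomes (dotted line at 1), for classes of 2 Mb bins in the naive (blue) and plasma (red) maps. Start with start contact goes from 1.99 to 2.98 and start with end contact from 1.09 to 0.579.

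Compartments were largely shared, with the gene Ell2 among the loci that moved most toward the active A compartment. The first component, which is positive in A and negative in B, went from -0.110 to 1.10 SD units in the bin of Ell2 (chromosome 13, 75500001 to 76000000), a change above 99.96% of bins. The bin of Jchain (chromosome 5, 88500001 to 89000000) went from -0.370 to 0.330 and switched from B to A, a change above 99.57% of bins, but with 2 Mb bins its change had the opposite sign. Bcl6 went from 0.939 to 0.628, with a change of the opposite sign in 2 Mb bins (0.11), and the bins of Prdm1, Xbp1, Irf4, Atf4, Hspa5, Ern1, Pax5, Bach2, Ebf1, Igh, Igk and Igl were in A in both maps.

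Of 4662 bins of 500 kb, 9 (4.50 Mb) switched from B to A and 37 (18.5 Mb) from A to B, with a correlation of 0.964 between the maps across bins, which are not independent replicates. These counts depend on the minimum size of the component. With no minimum they were 69 and 206, and with 0.5 SD they were 0 and 6. The longest stretch from B to A lay on chromosome 1 at 61000001 to 62500000 and holds the plasma peak at 62246144 named above. The longest from A to B lay on chromosome 3 at 80500001 to 81500000, and a bin next to Ebf1, chromosome 11 at 45000001 to 45500000, also went from A to B. Bins from A to B held 179 naive and 95 plasma peaks, among them chromosome 13 at 10000001 (14 and 0) and at 111000001 (15 and 3), while bins from B to A held 57 and 65, a ratio of 1.14. Bins that stayed in B held 2966 and 2053 peaks (ratio 0.692) and bins that stayed in A 21629 and 23992 (ratio 1.11), so the ratio of the bins from B to A was close to that of bins that stayed in A. Across the 4662 bins the change in component and the change in peak number were correlated with r = 0.228 and rho = 0.181. Both had a two-sided p of 0.0001 in a permutation test that rotated the bins within chromosomes, the smallest that 10000 rotations can give. The relation with RNA was not analysed here.

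**Figure D4:**
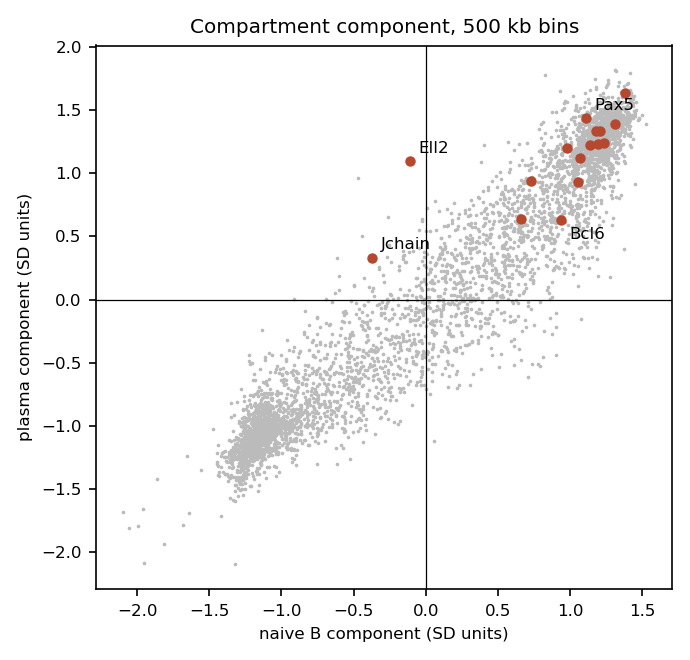
First compartment component of 500 kb bins in the naive map (horizontal axis) and the plasma map (vertical axis), in SD units of each chromosome. Grey points are the 4662 bins and red points the 16 loci. Ell2 goes from -0.110 to 1.10 and Jchain from -0.370 to 0.330.

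Between chromosomes, the immunoglobulin loci had less contact with the loci of B cell regulators in plasma cells, and plasma cell regulators had more contact with each other and with unfolded protein response loci at several pairs. Igk with Ebf1 went from 81 to 29 read pairs (log2 ratio of balanced contact -2.11), Igh with Ebf1 from 44 to 10 (-2.08) and Igh with Pax5 from 60 to 17 (-1.81). These were the largest losses: of the 19 such pairs 5 had a count interval below 0 and 3 had more contact in plasma cells, such as Igl with Bach2 (22 to 28 read pairs) and Jchain with Pax5 (8 to 11). Ell2 with Atf4 went from 5 to 20 read pairs (1.72), Ern1 with Ell2 from 6 to 20, Prdm1 with Xbp1 from 18 to 46 (1.21) and Hspa5 with Prdm1 from 13 to 30 (1.02). Not every pair of such loci gained: Xbp1 with Atf4, which had the most naive read pairs of its kind, went from 165 to 86 (-0.94, count interval -1.10 to -0.32), and Xbp1 with Ell2 from 14 to 6 (-1.11). Losses among other kinds of pair included Ern1 with Atf4 from 175 to 59 (-1.59), Igh with Xbp1 from 63 to 14 (-2.04) and Igh with Igl from 82 to 30 (-1.47).

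Over the 19 pairs of an immunoglobulin with a B regulator locus the median log2 ratio was -0.71. It lay at the percentile 1.57 of 10000 sets of random bins on the same chromosomes, whose median was -0.26. The read pairs of the 19 pairs went from 715 to 429, a log2 ratio per total between chromosomes of -0.50 (interval -0.68 to -0.33). Read pairs between strong A bins of different chromosomes gave -0.27 per total of the bins used. The standing of the median was lost with neighbouring bins included (-0.38, percentile 26.0) and against random bins of the same compartment component (percentile 3.88). No correction was made for the several kinds of pair compared. Over the 11 pairs of an unfolded protein response with a plasma regulator locus the median was 0.24 (percentile 94.2), and the read pairs gave 0.23 (0.02 to 0.44). Over the 5 pairs of plasma regulators it was 0.46 (percentile 91.9). The other 7 kinds of pair lay between the percentiles 7.80 and 87.5. Among them, the 12 pairs of an unfolded protein response with an immunoglobulin locus were at the percentile 15.2, while their read pairs went from 533 to 353, a ratio of -0.36 (-0.56 to -0.16), so a loss in read pairs was not particular to B regulator loci. Of all 114 pairs, 35 had more contact in plasma cells, and the count interval lay below 0 for 19 and above 0 for 10. Contact between chromosomes was lower in general: the median log2 ratio over 783071 pairs of 2 Mb bins was -0.24. The number with more contact is not corrected for that.

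**Figure D5:**
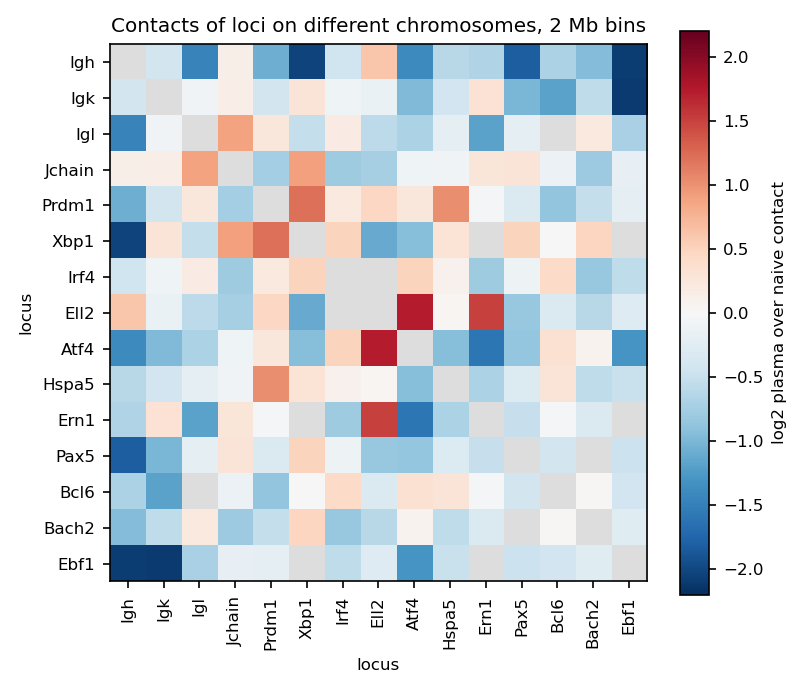
Log2 ratio of plasma over naive balanced contact for pairs of loci on different chromosomes, in 2 Mb bins, with both axes listing the loci. Grey cells are pairs on 1 chromosome. Igk with Ebf1 is at -2.11 and Ell2 with Atf4 at 1.72.

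The pairs of 2 Mb bins with the largest gains and losses by the fixed rule each had 0 read pairs in 1 map and at most 11 in the other, many in the bin at 120000001 to 122000000 of chromosome X, and they rest on few read pairs, chosen as the extremes of 783071 bin pairs. Among 46405 pairs with at least 50 read pairs in both maps together, a limit chosen after the maps were seen, the largest gain joined chromosome 5 at 150000001 with chromosome 15 at 92000001 (7 to 51 read pairs). Of the 10 largest losses, 4 joined the bin of Ebf1, chromosome 11 at 44000001 to 46000000, with other chromosomes, such as chromosome 10 at 96000001 (56 to 4) and at 94000001 (114 to 11).

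In the authors' lists of 1 Mb interactions the bins of Ebf1 and Pax5 had fewer interactions with other chromosomes in plasma cells. Ebf1 had 178 interactions with other chromosomes in naive B cells and 71 in plasma cells (percentile 1.65 of all bins), Pax5 258 and 168 (percentile 3.14), Igl 138 and 56 (percentile 3.94), and Igk 82 and 12 over its 4 bins (percentile 19.3). Prdm1 had 46 and 73 (percentile 84.5) and Irf4 37 and 63 (percentile 83.7). The other plasma regulator and unfolded protein response loci had fewer in plasma cells. Atf4 had 282 and 248 (percentile 12.3), Ern1 176 and 160 (percentile 20.1) and Xbp1 198 and 185 (percentile 23.0). Hspa5 had 184 and 181 and Ell2 10 and 7. Of 37 pairs of loci listed in at least 1 map, 16 were in both lists, 16 in the naive list alone and 5 in the plasma list alone: Prdm1 with Xbp1, Irf4 with Igl, Irf4 with Hspa5, Xbp1 with Bach2, and Hspa5 with Pax5. The lists held 60403 naive and 59188 plasma interactions, of which 87.1% (86.8 to 87.4%) and 85.8% (85.5 to 86.1%) joined different chromosomes. They shared 20266 interactions, 33.6% of the naive and 34.2% of the plasma list. The shared part was higher within chromosomes (53.0% of naive interactions) than between them (30.7%).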

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

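The tests of counting error, balancing and random ligation were chosen after the result was seen, while the others were written before their values were known; the test of myeloid markers was made stricter afterwards, by asking that it hold under every alternative. In the 2 Mb maps, the first 2 of the 3 bins after those of chromosome X were not used in the comparisons. Their identity was not tested; they were taken as chromosome Y from their number and place alone. They had contact with 1297 of 1328 other bins in naive B cells and 1294 in plasma cells, above the limit that a count of 0 allows.

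The labels of the plasma RNA library name a bone marrow sort and a culture. The neutrophil and monocyte markers had a median log2 ratio of -1.14, which met the condition set against marrow myeloid RNA. It is a ratio to a naive library that held such transcripts itself, with Lyz2 at 55.2 TPM and Csf1r at 42.5 TPM. The median alone therefore cannot show what the plasma library held. In that library Lyz2 stood at 0.24 TPM, Csf1r at 0.014 TPM and Adgre1 at 0.17 TPM, which argues against much myeloid RNA for these markers only. With a pseudocount of 5 TPM the median was 0.067, still at the percentile 0.26 of random lists, and the sort described would remove Gr1+ cells. The median of the cell cycle list was 2.91, which is consistent with dividing cells activated in culture. Recently formed plasma cells of the marrow may also divide. The list of B cell activation by LPS lay at the percentile 99.99 of random lists. Sdc1, which encodes the sort marker CD138, was at 11.1 TPM in naive B cells and 5.38 TPM in plasma cells. These values were not set as tests of the source, which stays open. By Xist and the Y-linked transcripts, the naive RNA came from male and the plasma RNA from female mice, so sex goes with the RNA comparison. This does not carry over to the contact maps, where interactions with chromosome Y were listed in both, 450 naive and 147 plasma. The sex of the cells in the maps was not tested.

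Contacts of immunoglobulin loci with B cell regulator loci were lower in the plasma map. Counting error alone is argued against by the summed read pairs, whose log2 ratio was -0.50 with an interval of -0.68 to -0.33. Read pairs between strong A bins of different chromosomes also fell, at -0.27 (-0.28 to -0.27) per total of the bins used. A loss is therefore not particular to these loci, most of which were in A. The compartment component of the loci stays open as a candidate explanation, since the median lay at the percentile 3.88 of random bins with a like component, inside the range set beforehand. A link to the lower RNA of Pax5 (-3.39) and Ebf1 (-1.30) was not tested. Ebf1 also had fewer listed interactions with other chromosomes in general, 178 in naive B cells and 71 in plasma cells. A loss particular to the pairs with immunoglobulin loci was not told apart from that.

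Contacts between the centromere ends of different chromosomes were more frequent in the plasma map. Repeats next to the ends are argued against by bins 10 to 20 Mb from the start, where the log2 ratio over the mean between chromosomes was 0.56. Balancing is argued against by the read pairs, whose ratio was 0.69 (interval 0.68 to 0.71), and dilution of the naive map by random ligation by the contacts between strong A bins, whose ratio was -0.22. No biological explanation was tested, and the culture that the protocol names goes with the plasma map alone.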

How the results depend on the processing

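The alternatives that left out bins at the extremes of nonzero entries, kept all bins with contacts or used recovered read pairs were chosen after the result was seen. No paired analysis was possible because each group held 1 library. For genes, lower counts moved to 1239 with a pseudocount of 5 TPM (1387 higher, 52.8%), and higher counts to 3680 with no TPM filter (2385 lower, 60.7%). Without centring the counts were 792 higher and 5890 lower (11.9% higher, against 42.0%, with the median of genes at -0.99). With TMM factors of the counts applied to TPM, which mixes 2 scales, 3454 were lower (26.3% higher, median at -0.31). These scalings subtract from every ratio, which moves genes across the threshold. Of 375 values of named genes under alternatives none changed sign where the ratio was at least 1, and 286 moved by more than the count interval. Of 161 list values 153 kept their side of the percentile limits, though lists inside the limits could turn in sign. Another 2, outside the limits, kept their side but turned in sign, 5 passed a limit and 1 lost it. The dendritic and basophil median passed a limit in opposite directions, at 2.70 and -2.33. The neutrophil and monocyte median became 0.067 with a pseudocount of 5 TPM and the interferon median -0.41 without centring. Peak sharing was 74.5% (naive) and 73.0% (plasma) in the better-scoring 50% of peaks, and 68.2% and 67.6% with equal numbers. The difference in contact between chromosomes was -4.27 points without extreme bins, -4.40 without X and Y and -4.53 in read pairs, and the slope difference from 2 to 20 Mb was -0.00051. Switches from B to A and from A to B numbered 9 and 14 in 2 Mb bins, 69 and 206 with no minimum and 0 and 6 with 0.5 SD, and 18 went from A to B with a component of log2 contacts. In 2 Mb bins the change of Jchain was -0.26. The immunoglobulin with B regulator median was -0.38 with neighbouring bins (percentile 26.0) and -0.71 against bins matched on component (percentile 3.88). Shared interactions were 39.3% and 40.1% in the stronger 50%, 61.9% and 55.1% with a neighbouring bin allowed, 34.0% and 35.0% without X and Y, and 34.0% of the naive list with equal numbers. The correlation of component and peak changes lay between 0.145 and 0.235. Apart from the scalings and the smaller or larger sets named, the cause was not tested. Row sums were equal by balancing, so leaving out extreme row sums was not run. Pairs of loci rest on few read pairs, which limits what they show.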

Other observations

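The single genes and chromosome pairs named here were chosen after the result was seen and no test was run on them, while the gene lists were planned. The immunoglobulin made by the plasma library was mostly IgM: Ighm went from 9261 to 92352 TPM, while the IgG constant genes Ighg, Ighg2c and Ighg1 reached 1034, 706 and 77.1 TPM. Light chains were mostly kappa, with Igkc at 109367 TPM and Iglc2 at 4111 TPM. The checkpoint gene Ctla4 was higher by 6.03 and the cytokine gene Il10 by 7.48. The chemokine receptor gene Ccr7 was lower, at -2.91.

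Genes of chromosome structure went both ways within a list whose median was -0.12 (percentile 48.5), with 5 of 22 members at least 2-fold higher and 5 lower. The condensin subunits Ncapg at 3.23, Ncaph at 2.81, Ncapg2 at 2.08, Ncapd2 at 1.98 and Smc2 at 1.54 were the higher members, while Ncaph2 was at 0.78, Ncapd3 at 0.76 and Smc4 at -0.00047. The cohesin loaders Nipbl at -1.44 and Mau2 at -1.24 were lower, as were the cohesin subunit Stag2 at -1.17 the organiser Satb1 at -1.37 and the topoisomerase Top2b at -1.23, while Ctcf was at -0.75 and the cohesin subunit Rad21 at 0.36, which is below 0 without centring. Without centring each ratio is lower by about 0.99. The nuclear envelope list had a median of -0.18 (percentile 39.5), with Lmnb1 at 1.42 and Sun2 at -1.58. Common reference genes had a median of 0.92 (percentile 86.0), which is -0.067 without centring and at the percentile 99.56 of lists matched on naive expression, and were not steady: Gapdh was at 3.11 and Actb at -0.70.

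Sex-linked genes moved in opposite directions between the RNA libraries. Xist went from 0.38 to 128 TPM, Ddx3y from 56.5 to 0.016 TPM and Kdm5d from 34.4 TPM to a listed 0. In the contact maps the X chromosome took 1.78% of read ends in naive B cells and 2.36% in plasma cells, and 450 naive and 147 plasma interactions involved chromosome Y. Of 190 pairs of chromosomes 183 had less contact in plasma cells, most of all 15 with 19 (log2 ratio -0.88), while 19 with X was at 0.20.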
